A study of Mus musculus with 8 samples.

How the data were processed

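Total RNA from 8 mouse liver samples was measured on a single-colour Illumina bead array, with 1 array per sample. Per the labels, the tissue came from 18-day-old C57BL animals, 4 samples were Cic-L-/- and 4 were wildtype, RNA was isolated on spin columns and checked on a Bioanalyzer, and the Cy3 labelling followed the array maker's standard protocol. The scanner, the software that summarised the beads and the array slide of each sample are not given in the sources used here. The labels number the samples 1 to 4 in each group without saying that they are separate animals, so the p-values measure the spread between these samples, which may be partly technical.

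The deposited signal table holds linear intensity values that the authors did not normalise between arrays: its lowest values lie near the scanner background and the medians differ between arrays. Of its 26821 rows, 25697 carry a probe ID and 1124 carry an array address only. The deposited normalised table holds log2 values, with no method given in words. Taking log2 of the deposited signal and applying quantile normalisation over all rows, with no background subtraction, gave the deposited log2 values to within 5.0e-05, and the deposited series matrix differed from that table by 0. Direction, scale and centring of both log2 tables are therefore known from the values. Medians of the deposited log2 values ran from 7.1614 to 7.1628 over the 8 arrays.

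The intensity values were the starting point. Most of the 1124 rows without a probe ID lay at background level, with a 95th percentile of 130.6 to 162.8 over the arrays. Some were brighter, and 5 exceeded 1000 on every array. All 1124 were taken as the negative controls. This is a reading of the values, since the deposited tables do not name these rows. A detection p was computed for each probe and array as the share of those rows that were at least as bright. Background was corrected with the normexp model on these controls (limma 3.58.1 under R 4.3.3, robust estimation, offset 16), followed by log2 and quantile normalisation. Probes with a detection p under 0.05 on at least 4 arrays were kept, which left 10300. Gene names came from the platform annotation: 23978 probes had 1 gene name, 0 had several and 1719 were unnamed here. Matching the annotation's gene IDs to a RefSeq gene table (assembly GRCm38.p6) changed 0 names. That table was used only for names and for the order of neighbouring genes, since no genome build is given with the arrays, and no coordinates are reported.

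Each gene was represented by its kept probe with the highest mean over the 8 arrays, and unnamed probes kept their own row. This gave 8255 features, of which 7637 were named genes and 618 unnamed probes. Among 1628 genes with more than 1 kept probe, 122 had some probes called and others not. By limma, 0 had probes called in opposite directions, and 1 had probes in opposite directions at an unadjusted p under 0.05. Differences between groups were tested with limma (lmFit and eBayes, two-sided, no covariate), adjusted by the Benjamini-Hochberg method over all features and called at an adjusted p under 0.05. Fold changes are on the normexp log2 scale with the offset, which understates changes of dim probes. Where a gene was not above background on any array of a group, its fold is given as "at least N-fold": the mean of the bright group against the mean, in the dim group, of the higher of the lowest detected signal on the array and the probe's own signal.

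Before the data were examined, 32 gene lists of liver pathways, regulators and cell types were fixed, and 30 had at least 5 tested members. Lists were tested with camera (preset inter-gene correlation 0.01), with camera using an estimated correlation, and with fry. Each was adjusted over the 30 lists. With an estimated correlation, camera also takes its degrees of freedom from the arrays rather than the genes, which lowers its power. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Members called are counted over all features and also adjusted over the list alone. Named genes followed a rule fixed at the same time: Cic, Etv1, Etv4 and Etv5; the 10 largest rises and 10 largest falls among called genes whose 4 values in each group did not overlap; up to 4 members of each list with the smallest adjusted p; and Cyp7a1, Cyp8b1, Cyp27a1, Abcb11, Abcc2, Slc10a1, Hnf4a, Cebpb, Foxa2, Tnf, Igf1, Afp and Alb. The rule gave 139 tested genes, of which 96 were called. A further 15 genes were named after their values were seen, to complete small counts or to describe the neighbours of Cic: Acss2, Apoc1, Apoc4, Apoe, Asns, Cbs, Cyp17a1, Cyp2a5, Cyp2g1, Dusp1, Fkbp5, Ghr, Hamp2, Igf2bp3 and Sqle. Aldh1a1, Aldh1a7, Zfp235, Zfp36, Blvrb, Pafah1b3 and Pglyrp1 were also named after their values were seen and stand outside these counts.

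The limma step was tested on simulated data with the observed means and spreads of the 8255 features, 4 samples per group and 200 changed genes. It recovered 18.6% of genes changed 1.5-fold, 62.5% of those changed 2-fold and 97.0% of those changed 4-fold, with 6 false among 123 calls. On simulated lists, camera called the shifted list and 0 of 30 unshifted lists. The simulated noise was independent between genes, so this could not show false calls from correlated genes. In the data the estimated correlation was as high as 0.53, for the macrophage list. The number of arrays limits the precision.

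The alternatives, fixed before the data were examined, were no background correction, median centring, the authors' deposited log2 tables, an offset of 50, other detection filters, all probes or the mean of a gene's probes, a variance trend with robust fitting, array weights, replicate number as a block, each array left out in turn and other thresholds. Leaving out the genes that neighbour Cic was added after the data were seen.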

Results

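Gene expression was measured in the livers of 18-day-old Cic-L-/- mice and of wildtype mice, with 4 samples in each group, to examine the part that Cic plays in metabolism. Cic encodes capicua, an HMG-box transcriptional repressor, and CIC-L is its long form. Each sample was hybridised to its own bead array carrying 25697 probes with an ID. Between 38.7% and 43.5% of these probes exceeded background on an array. The median signal of the control rows, a measure of background, was 138.5 to 141.9 on the Cic-L-/- arrays and 114.2 to 136.3 on the wildtype arrays. Pearson's r over all tested features, a correlation across genes that are not independent of each other, was 0.971 to 0.984 among Cic-L-/- arrays, 0.977 to 0.983 among wildtype arrays and 0.951 to 0.966 between the groups. The first principal component took 42.5% of the variance and separated the groups. On it, Cic-L-/- replicates 1 and 2 (-26.6 and -26.1) lay further from wildtype than replicates 3 and 4 (-14.8 and -12.9). The second component took 14.2% and set Cic-L-/- replicates 1 and 2 (13.7 and 12.8) apart from replicates 3 and 4 (-11.6 and -25.0). Transcripts of the Y-linked genes Eif2s3y and Kdm5d were above background on all 8 arrays.

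The single Cic probe was not above background on any array of either group. Its mean was 4.43 ± 0.12 on the log2 scale in Cic-L-/- liver and 4.66 ± 0.18 in wildtype liver (SD, n = 4), a difference of -0.23 ± 0.12 (SE, adjusted p = 0.504 over all probes). Its place on the transcript is not known here, so the probe checks nothing about the deleted part. The ETS factors Etv1, Etv4 and Etv5, which CIC is known to repress, were also too dim to test. Etv4 was above background on 1 Cic-L-/- array, 1 of the Etv1 probes on 1, and the Etv5 probe on 0 of the 8. Their log2 differences were 0.12 for Etv4, 0.03 for Etv5, and -0.08 and 0.06 for the Etv1 probes, with standard errors of 0.12 to 0.19. Of 10 tested CIC targets known from other studies, the cyclins Ccnd2 (log2 change 0.76 ± 0.14 SE, adjusted p = 0.00815) and Ccnd1 (0.55 ± 0.15, adjusted p = 0.0437) rose, and the other 8 did not pass. The Ccnd1 call ended with any 1 of the 8 arrays left out (highest adjusted p = 0.108), and with median centring or with all probes tested (highest 0.0556). Adjusted over the list alone, 2 rose. Dusp4 differed by 0.49 (adjusted p = 0.130) and the immediate early gene Egr1 by -1.11 (adjusted p = 0.176). The target list as a whole was not shifted (median 0.37, adjusted p = 0.160), but only 10 of its 22 genes could be tested. Relative to the wildtype mean, its mean was -0.06, -0.17, 0.33 and 0.41 in Cic-L-/- replicates 1 to 4.

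The 10 largest falls included 3 cytochrome P450 genes of the Cyp2b family, which oxidises drugs and steroids. Cyp2b9 had a mean log2 signal of 12.41 ± 0.16 in wildtype liver and 4.81 ± 0.22 in Cic-L-/- liver (SD, n = 4), where it was not above background on any array, so that it was at least 154-fold lower (adjusted p = 9.78e-11). Cyp2b13 was at least 55.6-fold lower (adjusted p = 9.95e-10) and Cyp2b23 at least 19.6-fold lower (adjusted p = 4.28e-10). The other genes among the 10 largest falls were the murinoglobulin Mug2 (37.9-fold), the neurotrophin receptor Ntrk2 (13.6-fold), apolipoprotein Apoc2 (10.7-fold), Lrtm1 (10.3-fold), Cyp2f2 (9.51-fold), nicotinamide N-methyltransferase Nnmt (9.35-fold) and proline dehydrogenase Prodh (8.79-fold). The 10 largest rises were those of the protease inhibitor Stfa1 (8.28-fold), acyl-CoA thioesterase Acot3 (7.99-fold), Cox6b2 (at least 5.96-fold), alpha-fetoprotein Afp (7.43-fold), the steroid dehydrogenase Akr1c18 (6.45-fold), macrophage receptor Marco (5.92-fold), Cstdc4 (at least 4.23-fold), the lipoprotein receptor Vldlr (5.09-fold), thyroxine-binding globulin Serpina7 (4.85-fold) and Igdcc4 (4.75-fold). In all 20 the 4 Cic-L-/- values lay on the same side of all 4 wildtype values. These folds and bounds hold for the background-corrected scale: without background correction the log2 change was -5.31 in place of -7.60 for Cyp2b9, -1.93 in place of -3.42 for Apoc2 and 1.24 in place of 2.90 for Cox6b2. Folds of genes with a group partly at background are approximate: Ntrk2 was above background on 2 Cic-L-/- arrays, Stfa1 and Marco on 1 wildtype array and Igdcc4 on 2.

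**Figure D1:**
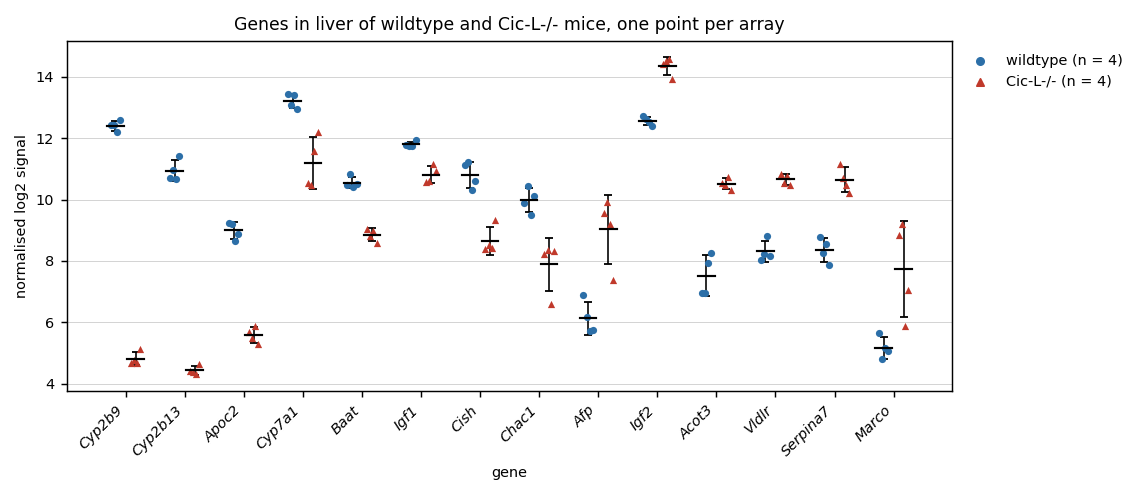
Normalised log2 signal (vertical axis) of 14 genes on each array, with circles for wildtype and triangles for Cic-L-/- liver; horizontal bars are means and error bars are SD, n = 4. Cyp2b9 averaged 12.41 in wildtype and 4.81 in Cic-L-/- liver, while the 4 Cic-L-/- values of Marco spread with an SD of 1.55.

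In all, 610 of 8255 tested features differed at an adjusted p under 0.05, 371 higher and 239 lower in Cic-L-/- liver, and 197 of them by at least 2-fold (108 higher, 89 lower). Named genes made up 354 of the rises and 222 of the falls, and for 35 features 1 group was not above background on any array. At an unadjusted p under 0.05 the count was 1854. The 2 groups of values did not overlap for 15.1% of the features tested, against 2.86% by chance. Leaving out 1 array lowered the count by over 1.5 times without Cic-L-/- replicate 1 (327), Cic-L-/- replicate 2 (348), wildtype replicate 1 (390), wildtype replicate 2 (399) or wildtype replicate 4 (396). The Marco call ended without Cic-L-/- replicate 1 or 2 or wildtype replicate 2, 3 or 4 (highest adjusted p = 0.0731), and also without background correction or without the detection filter (highest 0.0606). Probes of near-identical family members, such as those of Cyp2b, Acot and Stfa, cannot be separated here.

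In the neighbourhood of Cic, 5 of the 10 largest falls (Cyp2b9, Cyp2b13, Cyp2b23, Cyp2f2 and Apoc2) lay among the 250 protein-coding genes on either side, by the gene order of assembly GRCm38.p6, and 0 of the 10 largest rises did. Among the nearest 50 genes on each side, 12 of 39 tested genes were called, 8 of them lower. Among the next 200 on each side, 11 of 93 were called (11.8%), 7 of them higher, against 35 of 424 on the rest of the chromosome (8.25%) and 518 of 7081 on other chromosomes (7.32%). The falls among the nearest 50 were those of Cyp2b9, Cyp2b13, Cyp2b23, Cyp2f2 and Zfp235 (1.88-fold, adjusted p = 0.0324), and of Cyp2b10 (an approximate 5.70-fold, since it was above background on only 1 Cic-L-/- array, adjusted p = 0.00033), Cyp2a5 (2.83-fold, adjusted p = 4.0e-04) and Cyp2g1 (2.16-fold, adjusted p = 0.00119). Without background correction the log2 change of Cyp2b10 was -1.06 in place of -2.51. Zfp235 was above background on 1 Cic-L-/- array, and its call ended without any array but Cic-L-/- replicate 4 or wildtype replicate 1 (highest adjusted p = 0.0849), and without background correction or the detection filter (0.0858). Further along, Hamp2, a paralog of the iron hormone hepcidin, fell 5.99-fold (adjusted p = 0.0215), a call that ended without Cic-L-/- replicate 1 or 2 or wildtype replicate 3 (highest adjusted p = 0.0704), and also without the detection filter or with a variance trend (highest 0.0703). The 3 apolipoprotein genes that follow Apoc2 in this order did not pass: Apoc4 differed by -0.37 (adjusted p = 0.163), Apoc1 by 0.07 (adjusted p = 0.824) and Apoe by 0.03 (adjusted p = 0.941).

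In bile acid synthesis, 5 of 17 tested genes fell. Cyp7a1, the rate-limiting enzyme of the classical pathway, dropped 4.05-fold, from 13.21 ± 0.24 to 11.20 ± 0.84 (SD, n = 4, adjusted p = 0.00523). Baat, which conjugates bile acids to taurine or glycine, dropped 3.24-fold (adjusted p = 8.9e-05). Cyp8b1, the sterol 12-alpha-hydroxylase that sets the share of cholic acid, fell by 0.91 ± 0.21 (SE, adjusted p = 0.0238), Cyp2c70 by 0.67 ± 0.16 (adjusted p = 0.0292) and Cyp27a1 by 0.68 ± 0.19 (adjusted p = 0.0498). The other 12 did not pass, 7 of the 17 had a positive sign, and adjusted over the list alone 5 fell. The list was shifted down (median -0.18, adjusted p = 0.0205; adjusted p = 0.172 with an estimated correlation), and the call ended without Cic-L-/- replicate 4 (adjusted p = 0.0636). The calls of 3 members ended when 1 array was left out: Cyp8b1 without Cic-L-/- replicate 1, 3 or 4 or wildtype replicate 4 (highest adjusted p = 0.0594), Cyp2c70 without Cic-L-/- replicate 1 or 2 or wildtype replicate 1, 2 or 4 (0.0842), and Cyp27a1 without any array but wildtype replicate 3 (0.132). The Cyp27a1 call also ended with median centring, without the detection filter and with all probes tested (highest 0.0775). Adjusted over all probes on the array, another Cyp27a1 probe passed (-0.83, adjusted p = 0.0393), while this one (adjusted p = 0.0932) and the remaining one (-0.76, adjusted p = 0.203) did not.

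Bile acid transporters did not shift as a list (median -0.19, adjusted p = 0.338). The organic anion transporters Slco2b1 (2.41-fold, adjusted p = 0.00175) and Slco1a4 (1.65-fold, adjusted p = 0.0211) fell, the basolateral exporter subunit Slc51b rose 1.63-fold (adjusted p = 0.0144). The other 10 of 13 tested members did not pass, and adjusted over the list alone 2 rose and 4 fell. The canalicular bile salt pump Abcb11 differed by -0.45 ± 0.14 (SE, adjusted p = 0.0891), Abcc2 by -0.37 ± 0.18 (adjusted p = 0.257) and the uptake transporter Slc10a1, above background on 2 arrays of each group, by -0.19 ± 0.22 (adjusted p = 0.674). Among 17 tested liver transcription factors and nuclear receptors, Foxa1 (2.31-fold, adjusted p = 0.00138) and Cebpb (1.80-fold, adjusted p = 0.017) fell and Nr2f2 rose (at least 1.62-fold, adjusted p = 0.0124). The other 14 did not pass, among them Hnf4a (-0.24, adjusted p = 0.5), Foxa2 (-0.37, adjusted p = 0.432) and the bile acid receptor Nr1h4 (-0.41, adjusted p = 0.239). Adjusted over the list alone, 1 rose and 2 fell, and the list was not shifted (median -0.18, adjusted p = 0.165). The Slco1a4 call ended without Cic-L-/- replicate 1 or 2 or wildtype replicate 1, 2 or 3 (highest adjusted p = 0.0666), the Cebpb call without wildtype replicate 1 (0.051), and the Nr2f2 call without background correction (highest adjusted p over its alternatives 0.0713).

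Of the fetal liver genes 5 rose, and of the growth hormone and IGF axis 4 fell and 1 rose. Afp went from 6.13 ± 0.54 to 9.02 ± 1.13 (SD, n = 4, adjusted p = 0.0043). The growth factor Igf2 rose 3.48-fold (adjusted p = 8.97e-05), the cell cycle inhibitor Cdkn1c 3.11-fold (adjusted p = 8.9e-05), Peg3, above background on 1 wildtype array, 2.89-fold (adjusted p = 0.00773) and the RNA-binding protein Igf2bp3 1.79-fold (adjusted p = 0.00839). These were 5 of 13 tested fetal liver genes, the other 8 did not pass, and 9 rose when adjusted over the list alone (median 0.58, adjusted p = 2.57e-07; adjusted p = 0.0595 with an estimated correlation). In the growth hormone axis, the STAT5 target Cish fell 4.44-fold (adjusted p = 5.31e-04), Igfals 2.35-fold (adjusted p = 0.00301), Igf1, the main circulating mediator of growth hormone, 1.99-fold (adjusted p = 0.00509) and the receptor Ghr 1.53-fold (adjusted p = 0.0399). The binding protein Igfbp2 rose 4.13-fold (adjusted p = 2.82e-04), and the other 6 of 11 tested members did not pass. Adjusted over the list alone, 1 rose and 4 fell (median -0.34, adjusted p = 0.0205; adjusted p = 0.117 with an estimated correlation). The Ghr call ended without Cic-L-/- replicate 1 or 2 or any 1 wildtype array (highest adjusted p = 0.107).

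Of the cell cycle genes, 8 of 23 rose. The mitotic genes Birc5 (2.02-fold, adjusted p = 0.00674) and Plk1 (1.99-fold, adjusted p = 0.0163), thymidine kinase Tk1 (1.75-fold, adjusted p = 0.0144) and the replication licensing factor Mcm6 (1.66-fold, adjusted p = 0.0156) were among them, and the other 15 did not pass. Adjusted over the list alone, 15 rose. The list had the smallest p of the 30 tested with the preset correlation (median 0.63, adjusted p = 3.58e-09; adjusted p = 0.0595 with an estimated correlation), and its mean was higher than in any wildtype array on 4 of 4 Cic-L-/- arrays. The Mcm6 call ended without Cic-L-/- replicate 1 (adjusted p = 0.0505).

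In xenobiotic metabolism, the falls were led by Cyp2b9, Cyp2b13, Cyp2f2 and Cyp2b10, which neighbour Cic. They were followed by the retinal dehydrogenase Aldh1a1 (3.06-fold, adjusted p = 0.00186), which does not, and by the neighbour Cyp2a5. Of 28 tested members 8 fell and the other 20 did not pass; adjusted over the list alone, 1 rose and 10 fell (median -0.24, adjusted p = 7.09e-06; adjusted p = 0.0595 with an estimated correlation). Sex-biased liver genes, a list that mixes genes higher in adult males with genes higher in adult females, had 8 tested members. Cyp2b9 and Cyp2b13, which it shares with the xenobiotic list, Nudt7 (2.45-fold, adjusted p = 0.00169) and Cyp17a1 (1.95-fold, adjusted p = 0.0144) fell, Acot3 rose, and the other 3 did not pass; adjusted over the list alone, 2 rose and 5 fell. The list was shifted down (median -0.77, adjusted p = 8.03e-04; adjusted p = 0.0595 with an estimated correlation). Without the genes that neighbour Cic, an alternative chosen after seeing the data, neither list kept its call: the adjusted p was 0.0662 for the 23 remaining xenobiotic genes and 0.646 for the 6 remaining sex-biased genes. The sex-biased call also ended with only probes bright on all 8 arrays (adjusted p = 0.602).

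With the preset correlation, lipid lists were shifted down for cholesterol and fatty acid synthesis and up for oxidation, and not with an estimated one (adjusted p = 0.103, 0.162 and 0.0595). In cholesterol synthesis and uptake, farnesyl diphosphate synthase Fdps fell 2.23-fold (adjusted p = 0.0105), Msmo1 1.89-fold (adjusted p = 0.0259), Sqle 1.78-fold (adjusted p = 0.0437) and the regulator Srebf2 1.74-fold (adjusted p = 0.0268), while the feedback regulator Insig1 rose 2.05-fold (adjusted p = 0.0266). The other 9 of 14 tested members did not pass, 1 rose and 5 fell when adjusted over the list alone, and the list was shifted down (median -0.28, adjusted p = 0.00353; adjusted p = 0.103 with an estimated correlation). In fatty acid and triglyceride synthesis, Lpin1 (3.13-fold, adjusted p = 8.96e-04), Thrsp (at least 2.75-fold, adjusted p = 0.0043), the carbohydrate-responsive factor Mlxipl (2.41-fold, adjusted p = 0.00397) and Acss2 (1.47-fold, adjusted p = 0.038) fell, the desaturase Fads2 rose 1.80-fold (adjusted p = 0.0133). The other 11 of 16 did not pass. Adjusted over the list alone, 2 rose and 4 fell (median -0.22, adjusted p = 0.0338; adjusted p = 0.162 with an estimated correlation). The list call ended without Cic-L-/- replicate 2 (adjusted p = 0.0677) or wildtype replicate 4 (adjusted p = 0.0821), and with only probes bright on all 8 arrays (adjusted p = 0.241). Fatty acid oxidation and PPAR alpha targets were shifted up (median 0.34, adjusted p = 0.0036; adjusted p = 0.0595 with an estimated correlation). The hydroxylase Cyp4a14 (2.02-fold, adjusted p = 0.00153) and Acot1 (1.98-fold, adjusted p = 0.0268) rose. The other 18 of 20 did not pass, and 3 rose when adjusted over the list alone. In cholesterol synthesis, calls ended without Cic-L-/- replicate 3 or wildtype replicate 1 or 4 for Msmo1 (highest adjusted p = 0.0723), and without Cic-L-/- replicate 1, 2 or 4 or wildtype replicate 1, 2 or 4 for Sqle (0.116). They also ended without Cic-L-/- replicate 1, 2 or 3 or wildtype replicate 1, 3 or 4 for Srebf2 (0.0759), and without Cic-L-/- replicate 2 or 3 or wildtype replicate 2, 3 or 4 for Insig1 (0.0796). With the mean of its 2 probes the Insig1 difference was 0.36 (adjusted p = 0.383), and its call also ended without the detection filter. Sqle, above background on 2 Cic-L-/- arrays, and Srebf2 lost their calls without background correction (highest adjusted p over other processing 0.106 and 0.0587), Sqle also with median centring, an offset of 50 or no detection filter, and Msmo1 with median centring (0.0621). The Acss2 call ended without Cic-L-/- replicate 1 or 2 or wildtype replicate 1, 2 or 4 (0.105), and the Acot1 call without Cic-L-/- replicate 1 or 2 or wildtype replicate 1 or 2 (0.0809). They also ended with median centring for Acss2 (0.0535) and without the detection filter for Acot1 (0.053).

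Amino acid and urea metabolism, the unfolded protein response and glucocorticoid-responsive genes were shifted down with the preset correlation, and not with an estimated one (adjusted p = 0.0595, 0.0595 and 0.183). Prodh, alanine aminotransferase Gpt (3.12-fold, adjusted p = 0.0043), glycine N-methyltransferase Gnmt (-0.58, adjusted p = 0.0326) and cystathionine beta-synthase Cbs (-0.51, adjusted p = 0.0471) fell, and urocanase Uroc1 rose 1.77-fold (adjusted p = 0.0163). The other 17 of 22 tested amino acid genes did not pass, and adjusted over the list alone 1 rose and 5 fell (median -0.31, adjusted p = 5.38e-04; adjusted p = 0.0595 with an estimated correlation). Of 18 genes of the unfolded protein and integrated stress response, 7 fell, among them the glutathione-degrading enzyme Chac1 (4.28-fold, adjusted p = 0.006), the chaperone Hspa5 (2.08-fold, adjusted p = 0.00523), the transcription factor Xbp1 (1.73-fold, adjusted p = 0.00674) and the co-chaperone Dnajc3 (1.71-fold, adjusted p = 0.00736). Asparagine synthetase Asns rose 2.75-fold (adjusted p = 0.00847). The other 10 did not pass, and 1 rose and 10 fell when adjusted over the list alone (median -0.52, adjusted p = 1.13e-05; adjusted p = 0.0595 with an estimated correlation). Of 15 glucocorticoid-responsive genes, Gadd45g (5.08-fold, adjusted p = 1.26e-04), Tsc22d3 (2.15-fold, adjusted p = 0.0184), Dusp1 (2.12-fold, adjusted p = 0.0224), Klf9 (1.99-fold, adjusted p = 0.0129) and Fkbp5 (1.49-fold, adjusted p = 0.0374) fell. The kinase Sgk1 rose 2.02-fold (adjusted p = 0.00731), the other 9 did not pass, and adjusted over the list alone 1 rose and 6 fell (median -0.38, adjusted p = 0.0159; adjusted p = 0.183 with an estimated correlation). Calls ended without any array but Cic-L-/- replicate 1 for Gnmt (highest adjusted p = 0.0857), without any of the 8 for Cbs (0.129) and without Cic-L-/- replicate 1 for Uroc1 (0.0516). They ended without Cic-L-/- replicate 1 or 2 for Tsc22d3 (0.0621), without Cic-L-/- replicate 1 or wildtype replicate 1 or 2 for Dusp1 (0.0713), and without any array but wildtype replicate 4 for Fkbp5 (0.0964). With the mean of its 2 probes the Gnmt difference was -0.09 (adjusted p = 0.871). Median centring ended the calls of Cbs and Fkbp5, and testing all probes that of Cbs (highest adjusted p = 0.0574 and 0.0658).

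Of the genes of secreted hepatocyte proteins, 6 fell and 1 rose. Apoc2, Apoc3 (2.24-fold, adjusted p = 0.00271) and the complement component C9 (2.27-fold, adjusted p = 0.00345) were among 6 of 35 tested genes that fell, Serpina7 rose, and the other 28 did not pass; adjusted over the list alone, 2 rose and 9 fell. The list was shifted down (median -0.09, adjusted p = 0.00808; adjusted p = 0.0595 with an estimated correlation). Its Alb probe lay near background, at 5.33 ± 0.51 in Cic-L-/- and 6.01 ± 0.54 in wildtype liver (SD, n = 4), and differed by -0.68 (adjusted p = 0.2), so that it says little about albumin.

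The lists of macrophage, neutrophil and lymphocyte markers were shifted up in Cic-L-/- liver with the preset correlation, and not with an estimated one (adjusted p = 0.216, 0.162 and 0.163). The macrophage markers Marco, Adgre1 (2.74-fold, adjusted p = 0.0156), C1qc (2.26-fold, adjusted p = 0.0166) and Folr2 (2.01-fold, adjusted p = 0.00565) rose. The other 12 of 16 did not pass, and 5 rose when adjusted over the list alone (median 0.70, adjusted p = 7.09e-06; adjusted p = 0.216 with an estimated correlation). Among 12 neutrophil markers, S100a9 (2.28-fold, adjusted p = 0.00281), Ltf (1.72-fold, adjusted p = 0.0124), S100a8 (1.71-fold, adjusted p = 0.0304) and Chil3 (1.65-fold, adjusted p = 0.0452) rose. The remaining 8 did not pass, and 7 rose when adjusted over the list alone (median 0.68, adjusted p = 1.13e-05; adjusted p = 0.162 with an estimated correlation). The antigen presentation genes Cd74 (2.41-fold, adjusted p = 0.0169) and H2-Ab1 (1.97-fold, adjusted p = 0.0338), Klrd1 (1.95-fold, adjusted p = 0.0383) and the B cell gene Cd79a, a neighbour of Cic (1.71-fold, adjusted p = 0.0374), rose among 12 lymphocyte markers. The other 8 did not pass, and 7 rose when adjusted over the list alone (median 0.73, adjusted p = 6.89e-05; adjusted p = 0.163 with an estimated correlation). Among those 8, the antigen presentation genes H2-Eb1 and H2-Aa differed by 0.76 each. Cd3g differed by 0.70, Cd8b1 by 0.66, Ccl5 by 0.37, Cd2 by 0.31, Cd79b by 0.25 and Ms4a1 by 0.04. Since the list includes antigen presentation genes, its shift was not tied to lymphocytes alone. The groups of values overlapped for Klrd1, which was above background on 2 wildtype arrays. The rise was uneven: relative to the wildtype mean, the macrophage list mean was 1.33 and 1.27 in Cic-L-/- replicates 1 and 2, and 0.24 and 0.40 in replicates 3 and 4. The lymphocyte list mean was 1.00, 0.91, 0.33 and 0.37 in Cic-L-/- replicates 1 to 4. The neutrophil list mean was 0.88, 0.83, 0.15 and 0.72, with replicate 3 below wildtype replicate 3 (0.16; exact permutation p = 0.0571). The calls of Adgre1 and Cd74 ended without Cic-L-/- replicate 1 (adjusted p = 0.0524 and 0.0558), and C1qc without Cic-L-/- replicate 2 (0.053). Those of S100a8 and H2-Ab1 ended without Cic-L-/- replicate 1 or 2 or wildtype replicate 1 or 2, and that of H2-Ab1 also without wildtype replicate 4 (highest 0.0838 and 0.1). The calls of 3 others ended without most single arrays: Chil3 without any array but wildtype replicate 3 (0.126), Cd79a without any array but Cic-L-/- replicate 3 or wildtype replicate 4 (0.101), and Klrd1 without any array but Cic-L-/- replicate 4 or wildtype replicate 2 (0.107). Other processing ended the calls of Cd79a and Klrd1 (without background correction, with median centring or without the detection filter; highest adjusted p = 0.0647 and 0.0747) and H2-Ab1 (without the detection filter, 0.0664). It also ended those of S100a8 (median centring, 0.0535) and Chil3 (without the detection filter, with all probes or with the mean of probes, highest 0.155).

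Of the NF-kB targets 2 rose, and of the interferon-responsive genes 2. The chemokines Ccl4 (2.84-fold, adjusted p = 0.0043) and Cxcl10 (1.78-fold, adjusted p = 0.00773) rose. Without background correction the log2 change was 0.56 in place of 1.51 for Ccl4 and 0.36 in place of 0.83 for Cxcl10. The other 13 of 15 tested NF-kB targets did not pass, and 7 rose when adjusted over the list alone (median 0.37, adjusted p = 3.87e-04; adjusted p = 0.128 with an estimated correlation). That call ended with only probes bright on all 8 arrays (adjusted p = 0.059). The NF-kB list mean was 0.56, 0.60, 0.30 and 0.22 in Cic-L-/- replicates 1 to 4, beside 1.33, 1.27, 0.24 and 0.40 for the macrophage list. Tnfaip3 differed by 0.60 (adjusted p = 0.0525), and the probe for Tnf, above background on 1 array, was not tested. Among 19 interferon-responsive genes, Ifi27l2a (3.66-fold, adjusted p = 0.0107) and Gbp2 (1.79-fold, adjusted p = 0.0137) rose. The other 17 did not pass, and 3 rose when adjusted over the list alone (median 0.12, adjusted p = 0.0305; adjusted p = 0.365 with an estimated correlation). That call ended without Cic-L-/- replicate 1 (adjusted p = 0.132) or 2 (adjusted p = 0.136), and the list mean was 0.51 and 0.51 in these and 0.15 and -0.00 in Cic-L-/- replicates 3 and 4 (exact permutation p = 0.0857). Acute phase proteins were not shifted (adjusted p = 0.424, with a median of 0.17 and a mean of -0.02): the interleukin 1 antagonist Il1rn rose at least 1.30-fold (adjusted p = 0.0247), the other 20 of 21 did not pass, and 2 rose and 1 fell when adjusted over the list alone. Orm1 differed by -2.32 ± 0.69 (SE, adjusted p = 0.067), Apcs by 0.71 (adjusted p = 0.0626) and Hamp by -1.08 (adjusted p = 0.206). The Il1rn call ended without Cic-L-/- replicate 1 or 2 or wildtype replicate 2, 3 or 4 (highest adjusted p = 0.0695), and also without background correction, with median centring or with an offset of 50 (highest 0.0988).

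**Figure D2:**
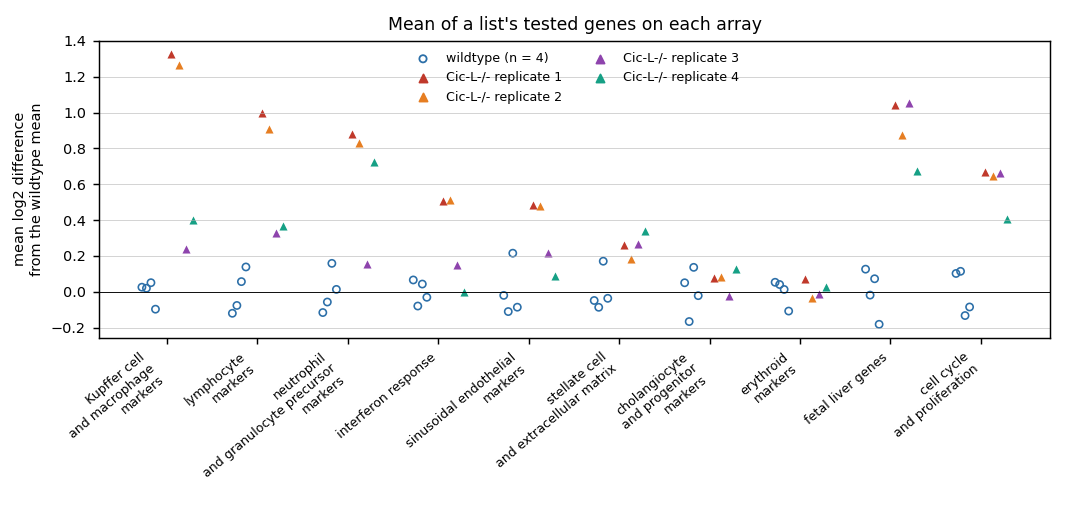
Mean log2 difference from the wildtype mean (vertical axis) over the tested genes of 10 lists (horizontal axis) on each array, with open circles for wildtype and triangles for the 4 Cic-L-/- replicates. Macrophage markers stood at 1.33 and 1.27 in Cic-L-/- replicates 1 and 2 and at 0.24 and 0.40 in replicates 3 and 4, while the erythroid markers stayed between -0.11 and 0.07 on all arrays.

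Among markers of other liver cells, 1 endothelial, 3 stellate and 1 cholangiocyte gene rose. Sinusoidal endothelial markers were shifted up (median 0.31, adjusted p = 0.00242; adjusted p = 0.245 with an estimated correlation), and the receptor Tie1 rose 1.98-fold (adjusted p = 0.0272). The other 20 of 21 did not pass, and 1 rose when adjusted over the list alone. The endothelial list mean was 0.49 and 0.48 in Cic-L-/- replicates 1 and 2, and 0.22 and 0.09 in replicates 3 and 4, against 0.22 in wildtype replicate 3 (exact permutation p = 0.0857). Of 24 stellate cell and matrix genes, Thy1 (2.23-fold, adjusted p = 0.0266), vimentin Vim (1.97-fold, adjusted p = 0.015) and Spon2 (1.51-fold, adjusted p = 0.0401) rose. The other 21 did not pass, and 7 rose when adjusted over the list alone (median 0.28, adjusted p = 0.00707; adjusted p = 0.128 with an estimated correlation), a call that ended with only probes bright on all 8 arrays (adjusted p = 0.0566). The groups of values overlapped for Thy1, which was above background on 1 wildtype array. The keratin Krt23 rose 1.76-fold (adjusted p = 0.00773) among 6 cholangiocyte and progenitor markers, of which 1 rose and 1 fell when adjusted over the list alone, and that list was not shifted (median 0.09, adjusted p = 0.5). The Tie1 call ended without Cic-L-/- replicate 1 or 3 or wildtype replicate 1 or 2 (highest adjusted p = 0.0838) and the Thy1 call without Cic-L-/- replicate 1 or 2 or wildtype replicate 1, 2 or 4 (0.0747). The Vim call ended without Cic-L-/- replicate 1 (0.0516) and the Spon2 call without any array but Cic-L-/- replicate 1 (0.105). Tie1 and Thy1 also lost their calls without background correction or without the detection filter (highest 0.0537 and 0.0569), and Spon2 with median centring (0.0564).

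The remaining lists were not shifted. In glucose and glycogen metabolism (median -0.17, adjusted p = 0.433), glycogen synthase Gys2 rose 2.66-fold (adjusted p = 0.0101), Gpt and glycogen phosphorylase Pygl (1.66-fold, adjusted p = 0.0367) fell. The other 13 of 16 did not pass, and adjusted over the list alone 2 rose and 2 fell. In the circadian clock list, the clock output gene Dbp rose 2.29-fold (adjusted p = 0.00513), Per3 rose at least 1.11-fold (adjusted p = 0.0365), Nfil3 fell 1.59-fold (adjusted p = 0.0123) and the other 11 of 14 did not pass. Adjusted over that list alone, 2 rose and 1 fell, and its median of 0.07 and mean of 0.02 stood against a test direction of down (adjusted p = 0.939). By limma, 0 of 13 antioxidant and NRF2 targets were called over all features or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (median -0.20, adjusted p = 0.319). Of 8 erythroid markers 0 were called over all features or over the list alone by limma, 0 had an unadjusted p under 0.05, and the median of -0.01, mean of 0.01 and test direction of up differed in sign (adjusted p = 0.939). Adipocyte and skeletal muscle markers, of which 5 could be tested, had 0 called by limma in both ways, 2 at an unadjusted p under 0.05 and a median of -0.06 (adjusted p = 0.772). Only 3 exocrine pancreas markers and 2 sex-linked genes could be tested, too few for the list test. The elastase Cela2a fell 1.67-fold (adjusted p = 0.0403), Pnliprp1 differed by 1.16 (adjusted p = 0.0531), Cela1 by -0.30, Eif2s3y by -0.17 and Kdm5d by 0.09. Adjusted over the list alone, 1 pancreas marker rose, 1 fell and 0 sex-linked genes were called, with 0 at an unadjusted p under 0.05. Leaving out 1 array ended the calls of Pygl (any array but Cic-L-/- replicate 4 or wildtype replicate 1), Per3 (any array but Cic-L-/- replicate 1 or wildtype replicate 3) and Cela2a (any array but wildtype replicate 4), with highest adjusted p-values of 0.103, 0.096 and 0.113. Other processing also ended them: Pygl without the detection filter or with the mean of probes (highest 0.0571), Per3 without background correction, with median centring, an offset of 50 or a variance trend (0.142), and Cela2a without background correction, with median centring or without the detection filter (0.0842).

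**Figure D3:**
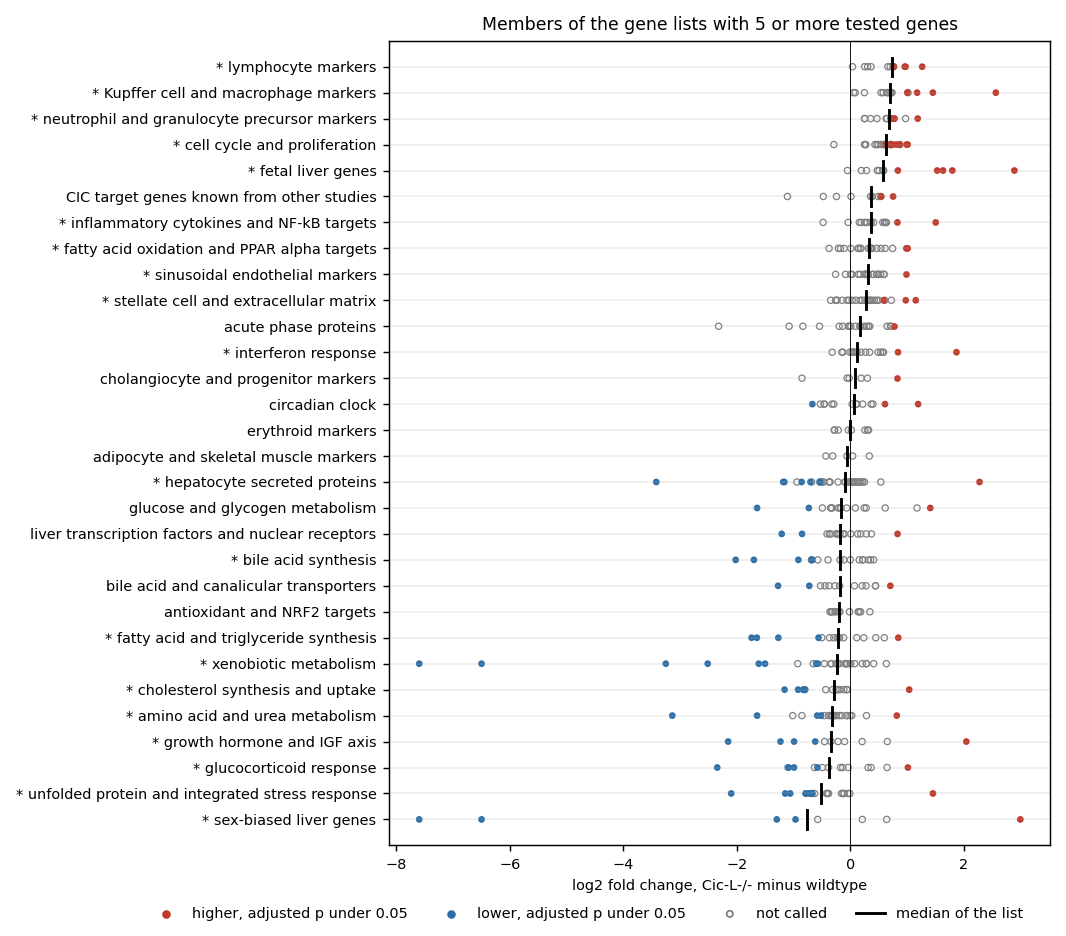
Log2 fold change of each tested member (horizontal axis, Cic-L-/- minus wildtype) in the 30 lists with at least 5 tested genes (vertical axis, ordered by median). Filled red and blue points are called higher and lower, open points are not called, black bars are medians, and an asterisk marks the 20 lists shifted by camera with the preset correlation; points of genes at background in a group are fitted values, not bounds.

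Of the 30 lists tested, 20 were shifted by camera with the preset correlation, 10 up and 10 down. With an estimated correlation camera called 0 (lowest adjusted p = 0.0595), and 11 had an unadjusted p under 0.05; fry called 20 in a single direction and 28 in either direction. Medians with genes at background set to their bounds were the same in all lists. By fry the transporter list (adjusted p = 0.0187) and the transcription factor list (adjusted p = 0.0102) also moved one way, and the interferon (adjusted p = 0.105) and endothelial (adjusted p = 0.0541) lists did not pass.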

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

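Of the tests of explanations, those of chance and of background signal were written before their results were seen; the other 4, and the comparisons beside them, were chosen after. Among named genes, 15 groups of 4 arrays held 1 array whose gap to the nearest other exceeded Dixon's limit as a share of the range, out of 308 groups, and chance alone gives about 1 in 20 groups.

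In Cic-L-/- liver, replicate 3 stood apart for the bile salt pump Abcb11 (10.45, others 10.25 to 10.26; ratio 0.949), the stress gene Chac1 (6.60, others 8.23 to 8.36; 0.928), the tight junction gene Cldn7 (4.85, others 5.25 to 5.32; 0.854) and the muscle gene Myl1 (5.43, others 5.20 to 5.23; 0.877). Replicate 4 stood apart for the STAT5 target Cish (9.34, others 8.38 to 8.51; 0.861), the desaturase Fads2 (9.56, others 9.75 to 9.78; 0.857) and the chaperone Hspa5 (5.59, others 6.07 to 6.15; 0.856). Replicate 2 did so for Apoc4 (12.81, others 13.07 to 13.10; 0.904) and Cyp2b10 (4.48, others 5.09 to 5.15; 0.917).

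In wildtype liver, replicate 2 stood apart for the acute phase gene Apcs (9.24, others 8.49 to 8.57; 0.889) and for Nnmt (9.38, others 9.73 to 9.75; 0.938). Replicate 3 did so for the lipase Lpl (14.77, others 14.51 to 14.54; 0.885), the endothelial receptor Stab2 (7.97, others 8.13 to 8.14; 0.919) and Taldo1 (9.91, others 10.27 to 10.32; 0.889). Replicate 4 stood apart for the acute phase gene Orm1 (10.29, others 8.85 to 8.98; 0.906).

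The first pattern weighed was the count of 610 genes that differed between the groups. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes, the real split. The highest count in another split was 0 by limma. At an unadjusted p under 0.05 the other splits gave 175 to 838 genes, against 1854 in the real split. This argues against chance but does not exclude it. The other splits mix the groups, and the smallest p that a test over 35 splits can give is 0.0286. Background was lower on each wildtype array than on any Cic-L-/- array, though wildtype replicate 3 had nearly the background of the Cic-L-/- arrays. Its values were examined for the 468 genes called without it. They lay a median share of 0.203 of the way from the other wildtype arrays towards Cic-L-/- (interquartile range -0.054 to 0.413). That is nearer to wildtype, but it rests on 1 array, so background as a cause stays open. The effect of the genotype, and any unrecorded difference between litters or array slides, stays open and was not tested.

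The second pattern was the large falls among neighbours of Cic. The receptor CAR is known to drive Cyp2b10, and whether it drives the other neighbours that fell was not tested. Its own transcript, Nr1i3, differed by -0.10 (adjusted p = 0.803 by limma), which does not measure its activity. Lower activity of CAR was weighed with 13 CAR targets away from Cic. Their median was -0.0661 (bootstrap 95% interval over these genes -0.37 to 0.07), although Aldh1a1 (-1.61, adjusted p = 0.00186) and Aldh1a7 (-0.93, adjusted p = 0.0875) among them go with it. The median argues against lower CAR activity as the whole cause only as far as these targets depend on CAR in these livers. That dependence was not tested. DNA of another strain carried along with the targeted allele stays open. With Cyp2b genes left out, 19 of 128 tested neighbours were called, 11 of them higher, against 553 of 7505 other genes (odds ratio 2.19, 95% interval 1.26 to 3.62), and 8 fell (odds ratio for falls 2.32, 0.96 to 4.80), but that count kept Cyp2f2 and Apoc2, which had prompted the test. With only the 5 neighbours among the 10 largest falls left out, the odds ratio was 2.08 (1.18 to 3.47) for calls in either direction and 2.03 (0.79 to 4.38) for falls. With all Cyp2 genes left out as well, among them Cyp2a5 and Cyp2g1, it was 1.75 (0.94 to 3.05) in either direction, 1.18 (0.31 to 3.15) for falls and 2.05 (0.98 to 3.85) for rises, so the excess depends in part on the Cyp2 genes. The odds ratio intervals treat genes as independent, which neighbours of the same family may not be, so the intervals may be too narrow. The genotype itself also stays open and was not tested.

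The third pattern was the rise of macrophage, lymphocyte and neutrophil markers. Blood left in the tissue as the whole cause is argued against by the erythroid markers, which differed by 0.0127 (95% interval over arrays -0.09 to 0.12). The 4 bright ones differed by 0.09 on average: Alas2 by 0.30, Slc4a1 by 0.26, Hba-a1 by 0.02 and Tfrc by -0.21. The remaining erythroid markers lay near background, and a part of the rise from blood stays open. A lower share of hepatocytes would raise the other cell types alike. The first test of it did not decide: macrophage markers rose 0.49 more than endothelial markers, and the values of the groups overlapped (exact permutation p = 0.0857). Comparisons run because of that set the 3 immune lists together against each other list: the excess was 0.69 over erythroid and 0.64 over cholangiocyte markers, with no overlap (exact p = 0.0286 each, the smallest possible, not adjusted for the 4 comparisons), and 0.44 over stellate (exact p = 0.114) and 0.39 over endothelial genes (exact p = 0.0857). With bright members only, the excess over the 4 erythroid and 3 cholangiocyte genes left was 0.69 and 0.73 (no overlap). Over endothelial and stellate genes it was 0.48 (exact p = 0.0286) and 0.62 (exact p = 0.0571). The 3 cholangiocyte genes moved apart, with Krt23 at 0.82, Aqp1 at 0.19 and Wfdc2 at -0.85, so their mean says little about that cell type. These comparisons, chosen after the first test, do not settle whether a lower hepatocyte share was the cause. That share, more immune cells, more expression per cell and the genotype stay open.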

How the results depend on the processing

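Leaving out the genes that neighbour Cic was chosen after seeing the data; the other alternatives were chosen before. With 1 array left out, called genes ranged from 327 to 628 (610 with all arrays) and shifted lists from 18 to 20. Fewer arrays lower the power, but power alone does not account for this range. The count was 327 and 348 without Cic-L-/- replicates 1 and 2, and 505 and 628 without replicates 3 and 4. Many calls therefore depend on Cic-L-/- replicates 1 and 2. At an adjusted p under 0.1 the count was 979, by construction. With an estimated correlation camera shifted 0 lists, with 11 at an unadjusted p under 0.05, while fry shifted 20. The estimated correlation was 0.53, 0.38 and 0.34 for the macrophage, neutrophil and lymphocyte lists. It was -0.03 for fatty acid oxidation and -0.01 for secreted hepatocyte proteins, below the preset 0.01. A higher correlation therefore does not account for the lost calls of those lists. With an estimated correlation camera also takes its degrees of freedom from the few arrays, and with a preset one from the many genes. This lowers its power for every list, so the lost calls cannot be put down to correlation alone. The share of each was not tested. Other processing gave 491 to 741 genes and 16 to 20 lists, and leaving out the neighbours of Cic gave 587 genes and 18 lists. The Cic probe differed by -0.44 to -0.09 and was called in none of its alternatives, and without 1 array by -0.30 to -0.16.

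For the 154 named genes, 3029 combinations of gene and alternative had 0 reversals of a called gene. They had 266 losses and 77 gains of a call, and 13 sign differences where neither was called. No background correction, the authors' log2 table and the series matrix hold nearly the same values. Each gave 11 losses and 10 gains, so these are counted more than once. With replicate number as a block, 467 genes (438 shared) and 20 lists were called. Deviations of same-numbered arrays correlated at -0.03 to 0.05, against -0.04 to 0.03 for other pairs. Of the 4 same-numbered pairs, 0 were over 0.1 and 1 matched its own number best. These values gave no clear sign of pairing by number, but 4 pairs cannot exclude a shared litter or slide. A sex covariate was not run because both Y-linked genes were detected on all 8 arrays, and array slide was not run because it is not given in the sources used here. Signal near background limits Cic, the Etv genes, Tnf and Alb.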

Other observations

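No hypothesis beyond those weighed above was tested, and the genes given here were chosen after their values were seen. Beyond the genes already given, the mRNA decay factor Zfp36, a neighbour of Cic, fell by 1.06 ± 0.14 (SE, adjusted p = 0.00133, highest 0.00663 with 1 array left out). Biliverdin reductase Blvrb, also a neighbour of Cic, rose by 0.86 ± 0.17 (adjusted p = 0.0115, highest 0.038). Pafah1b3, the gene next to Cic, rose by 0.73 ± 0.15 (adjusted p = 0.0161), a call that ended without Cic-L-/- replicate 2 or wildtype replicate 1 (highest adjusted p = 0.0513). The peptidoglycan receptor Pglyrp1, another neighbour of Cic, rose by 1.04 ± 0.22 (adjusted p = 0.017), a call that ended without Cic-L-/- replicate 1 or wildtype replicate 2 (highest adjusted p = 0.0586).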
